A study of Homo sapiens with 9 samples.

How the data were processed

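The series holds poly(A)-selected RNA from HEK293 cells in 9 libraries: 3 from cells with UBE3D knocked out by CRISPR/Cas9 (KO), 3 from KO cells with UBE3D put back (addback) and 3 from wild-type cells (WT). RNA was extracted with TRIzol, per the labels. The labels mark the samples as pooled and do not say whether the libraries of a group came from separate cultures, so p-values here measure the spread between libraries of unknown independence. No library was left out, and 0 sample columns went unused.

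Per the submitters' processing notes, the programs used were cutadapt 1.8.1, STAR 2.5.2b and DESeq2 on hg38; the notes do not say which step each served. The counting program, the gene annotation behind the counts and the program that found downstream-of-gene regions are not given in the sources used here. The deposited count table gives counts per gene and library (unit: count) for 26485 genes, with gene length in bases (unit: other). Its column names carry KO, KO.U and WT; KO.U was taken as addback, since the authors' deposited comparison tables name the same group as KO with UBE3D. The authors' deposited result tables for genes and for downstream-of-gene regions give base means (unit: signal), fold changes and their standard errors (unit: log2), test statistics (unit: score) and p-values with adjusted p-values (unit: p-value). The deposited region tables also give region lengths in bases (unit: other). From the relation of fold to standard error, folds were shrunken in 3 of the authors' deposited tables and unshrunken in the region table of KO against WT, so the region folds of both comparisons are not on one scale. Region tables hold no values per library, so no test beyond the authors' was run on them; 6 of their region names occur more than once in the KO against WT table. Deposited region starts were raised by 1 base, and region coordinates are given as 1-based on hg38.

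Symbols were matched to GENCODE v29, 23900 directly and 26 through another symbol, of 26485; coordinates are hg38. A coding length was available for 18580 genes. The total counts per library ran from 23088295 to 37508780. Counts were fitted with edgeR 4.0.16 in R 4.3.3: filterByExpr by group left 21994 genes, library sizes were scaled with TMM factors, and 1 quasi-likelihood fit (robust) over all 9 libraries with genotype as the only term gave the contrasts KO against WT, addback against KO and addback against WT. A gene was called where its Benjamini-Hochberg adjusted p was under 0.05. Fold changes are log2 with standard errors from the fit, and CPM are means with SD over 3 libraries. Folds with a group near 0 counts are printed as "at least", with a floor of 3 counts over the group. For levels of single genes, exact permutation tests of 3 against 3 libraries were used, where the smallest possible two-sided p is 0.1.

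Replicate numbers in the titles were checked for pairing by correlating gene residuals of libraries with the same number. For addback against WT the correlations over all genes were 0.90, 0.61 and 0.74, so a fit with the replicate number as a block is given beside the main contrast. In both comparisons with KO the same-number correlations over all genes were -0.04 to 0.00. Among low-background genes they were 0.51, 0.21 and 0.60 for addback against WT, 0.07, 0.04 and 0.09 for KO against WT, and 0.04, 0.12 and 0.21 for addback against KO; pairing was taken as given only where every pair lay above 0.1. Replicates were compared for duplication by the spread of their counts, and no library was a copy of another (chi-square per degree of freedom of 1.99 to 44.5).

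Libraries were examined for counts over 566 tissue-restricted genes (odorant receptors, keratin-associated and other families chosen by symbol), of which 556 have a coding length. The median count per kilobase of coding sequence over these genes was taken as the background of each library, and the background of each gene was estimated from its coding length. After the data were seen, 5768 low-background genes were set apart: estimated background at most 10% of mean CPM and coding sequence at least 10% of the exons. The same edgeR steps were run on these genes alone, with TMM factors from these genes, and CPM called scaled CPM in the text use those factors for all genes. Further runs subtracted the estimated background, or 2 times that estimate.

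The 32 gene lists were fixed before the data were examined: cleavage and polyadenylation, Integrator, replication-dependent histones, histone pre-mRNA processing, mesenchymal and invasion, epithelial, collagen and matrix, cell cycle, p53 targets, anaphase-promoting complex, proteasome, ATF4 and unfolded protein response, heat shock, interferon-stimulated, antigen presentation, NF-kB, immediate early, TGF-beta and YAP, Wnt, sterol synthesis, fatty acid synthesis, hypoxia and glycolysis, nuclear-encoded respiratory chain, mitochondrially encoded, ribosomal protein, stemness, neural, kidney and adrenal, breast epithelial, blood, endothelial, and HECT and UBE3 ligase genes. Each list with at least 5 tested members was tested with camera of limma 3.58.1 (preset correlation 0.01), adjusted over lists, beside camera with an estimated correlation and fry. Genes at one chromosome were tested as lists in the same way.

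Genes named in the text follow a written rule: UBE3D and CPSF3 always; in both comparisons with KO, protein-coding genes past adjusted p 0.05 without overlap of CPM, the 8 highest and 8 lowest folds at mean CPM of at least 5 and 4 of each at 50 or more; 4 of each for addback against WT; 5 in each direction for returned genes; and up to 4 members of each list per direction with the smallest adjusted p. The rule was reapplied to the low-background genes after the data were seen. Regions are the 5 highest and 5 lowest past the authors' adjusted p 0.05 at or above the median base mean of called regions.

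Genes returned by addback were those called KO against WT and called in the opposite direction addback against KO. Both comparisons share the KO libraries, so the count was set beside that of independent lists per direction, and beside 20 simulated sets of unchanged groups sharing those libraries, without the correlation of same-number WT and addback libraries. For regions, the authors' fold was compared with the edgeR fold of the host gene. The next same-strand gene starting within 10 kb downstream of the end of the host gene was compared with 10000 random lists matched on expression. Confidence intervals of medians are bootstrap 95% intervals over genes or regions, which are not independent replicates.

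The steps were tested on counts simulated from the means and dispersions of the real libraries, with 200 genes changed in KO. Over all tested genes, 40% were recovered at 2-fold and 31% at 1.5-fold, with 6.58% false among the calls. Over low-background genes 100% were recovered at both sizes, with 6.98% false. Alternatives tried were DESeq2 1.42.0 size factors and its test, upper quartile factors, other filters, 6 libraries only, each library left out, the replicate block, an adjusted p of 0.01, an absolute log2 fold of at least 1, and all 10 splits of each 6 libraries into 3 and 3. Added after the data were seen were the low-background and subtraction runs, a 5% background limit, the limit held against the lowest group mean, leaving out WT and addback libraries 2 and 3, leaving out chromosome 9 and regions without coding bases. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.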

Results

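UBE3D is an E3 ubiquitin ligase, and the series concerns its link to CPSF3, the endonuclease (CPSF73) that cuts pre-mRNA at the poly(A) site. Libraries of HEK293 cells with UBE3D knocked out (KO), of KO cells with UBE3D put back (addback) and of wild-type cells (WT), 3 each, were compared gene by gene. Levels are mean scaled CPM ± SD of 3 libraries, and fold changes are log2 ± standard error.

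UBE3D RNA (chromosome 6, 82892398-83065841, minus strand) was 19.2 ± 1.67 CPM in KO, 30.6 ± 5.12 in WT and 4260.3 ± 419 in addback cells (exact permutation p = 0.1 for each pair of groups, the smallest possible). UBE3D RNA was therefore still present in KO cells. It was lower in KO than in WT by a log2 fold of -0.65 ± 0.13 (edgeR adjusted p = 0.0011), while the scaling over all genes gave -0.28 ± 0.16 (adjusted p = 0.142). UBE3D counts as a low-background gene through its addback level, and with the background subtracted the fold was -0.51 (edgeR adjusted p = 0.00263), or -0.32 with it subtracted at 2 times its estimate (adjusted p = 0.0112). The addback exceeded KO by 7.79 ± 0.12 (adjusted p = 4e-12) and WT by 7.14 ± 0.12 (adjusted p = 5.7e-12). CPSF3 (chromosome 2, 9423537-9473110, plus strand) differed little in RNA level: 158 ± 2.43 CPM in KO, 147 ± 8.18 in WT and 151 ± 4.07 in addback. Its log2 fold was 0.11 ± 0.04 in KO against WT (adjusted p = 0.0482), a call lost without KO 1 (0.110), KO 2 (0.0718), KO 3 (0.0853), WT 1 (0.198) or WT 2 (0.138). CPSF3 was not past the edgeR test from KO to addback (-0.06 ± 0.04, adjusted p = 0.27) or between addback and WT (0.05 ± 0.04, adjusted p = 0.445). The exact permutation p for CPSF3 was 0.1 in both comparisons with KO, the smallest possible, and 0.5 in addback against WT.

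**Figure D1:**
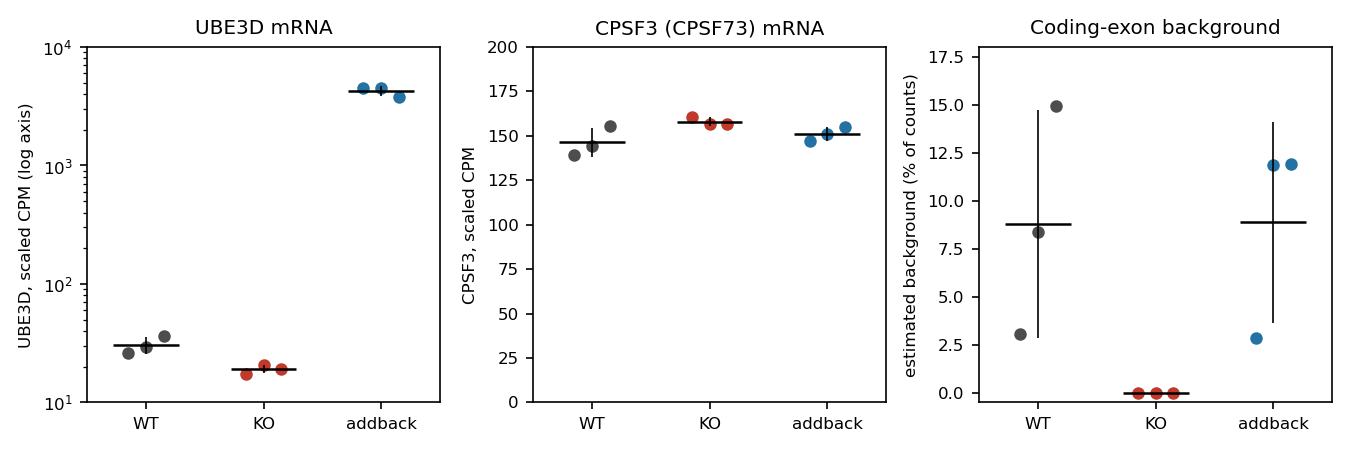
UBE3D (log axis) and CPSF3 in scaled CPM, and estimated coding background in percent of each library, for KO, addback and WT; points are libraries, lines means and bars SD over 3 libraries. UBE3D was 19.2 CPM in KO, 30.6 in WT and 4260.3 in addback, and background ran from 0% in KO to 14.9% in a WT library.

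Genes of organs unrelated to kidney cells had reads in WT and addback libraries and few in KO libraries. Odorant receptors of the nose (379 genes) held 9653, 31602 and 37802 counts in WT libraries 1 to 3, 8449, 39892 and 40357 in the addback libraries, and 150, 143 and 219 in KO. Over 566 tissue-restricted genes, 95.1% to 95.8% had a count in each WT or addback library, against 13.4% to 17.0% in KO. Spread over coding sequence, such reads would fill 3.06%, 8.37% and 14.9% of WT libraries 1 to 3, and 2.85%, 11.9% and 11.9% of the addback libraries. CSMD3 (chromosome 8, 112222930-113437013, minus strand), a giant membrane protein of neurons, was at least 1380.0-fold lower in KO than in WT and at least 835-fold higher in addback than in KO. The mucin MUC17 stood at 0.125 CPM in KO, 147 ± 79.6 in WT and 231 ± 143 in addback, and MUC16 at 0.172, 138 ± 84.1 and 195 CPM.

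Counted over all 21994 tested genes, 13542 were called in KO against WT (5315 higher, 8227 lower, 39.2% higher), 13155 in addback against KO (8364 higher, 4791 lower, 63.6% higher) and 566 in addback against WT (375 higher, 191 lower, 66.3% higher). With a log2 fold of at least 1 these counts were 7556, 7509 and 162, and 7292 of the 7556 were lower in KO. Upper quartile factors moved the splits to 3331 higher and 9947 lower (25.1% higher), 9396 and 3257 (74.3%), and 697 and 856 (44.9%). Scaling on low-background genes gave 1774 and 12000 (12.9%), 11323 and 1265 (89.95%), and 1021 and 1041 (49.5%), and DESeq2 factors gave 453 and 525 (46.3%) in addback against WT. The median fold of all genes shifted by -0.38 and 0.34 in the comparisons with KO when scaled on low-background genes, and by -0.22 and 0.18 with upper quartile factors. The authors' deposited tables hold 14834 called genes in KO against WT (5032 higher, 9802 lower) and 14767 in addback against KO (9482 higher, 5285 lower). Of the 7901 genes past the fold threshold of the authors' deposited table in KO against WT, 0.61% were low-background genes. The comparisons that follow use the 5768 low-background genes, a choice made after the data were seen, unless another set is named. Among them 3046 were called in KO against WT (1431 higher, 1615 lower), 2131 in addback against KO (1113 higher, 1018 lower) and 2362 in addback against WT (1126 higher, 1236 lower). In the scaling over all genes the median of these genes lay at 0.36 in KO against WT, -0.34 in addback against KO and 0.02 in addback against WT, so small folds change sign between both scalings. The limit is set on the mean of all libraries, so a gene high in one group can enter for that reason. Against the lowest group mean 5161 genes meet it, of which 2709 were called in KO against WT (1273 higher, 1436 lower).

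Sterol synthesis genes were lower in KO than in WT cells. INSIG1 (chromosome 7, 155297776-155310235, plus strand), the SREBP target that holds SREBP back in the endoplasmic reticulum, fell from 426 ± 17 CPM in WT to 154 ± 13.3 in KO (-1.47 ± 0.05, edgeR adjusted p = 3.9e-11). HMGCS1, which makes HMG-CoA, went from 879 ± 21.7 to 391 ± 28.9 CPM (-1.17 ± 0.05, adjusted p = 1.3e-10), and the acetyl-CoA acetyltransferase ACAT2 from 302 ± 6.7 to 148 ± 2.77 (-1.03 ± 0.04, adjusted p = 4.1e-11). Of 21 sterol genes 19 were called lower and 0 higher, the same number adjusted over the list alone. Their median was -0.65, or -0.28 in the scaling over all genes (camera adjusted p = 1.7e-36, adjusted p = 0.0181 with an estimated correlation). The lanosterol synthase gene LSS was lower as well (-0.93 ± 0.05). Of 10 fatty acid genes 7 were called lower and 2 higher (the same over the list alone), among them SCD, the stearoyl-CoA desaturase (-0.86 ± 0.06), and the carrier gene FABP5 (0.59 ± 0.06). The fatty acid list had a median of -0.35, or 0.01 in the scaling over all genes (camera adjusted p = 0.0122, adjusted p = 0.408 with an estimated correlation).

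Immediate early genes and the 6 low-background genes among 65 tested replication-dependent histone genes were higher in KO than in WT. Histone mRNAs of this class normally end without a poly(A) tail, so poly(A)-selected libraries hold their polyadenylated forms, and reads of near-identical histone copies can be assigned to the wrong copy. All 65 histone genes together had a median of -1.04 and a mean of -1.58 in the scaling over all genes, with 10 called higher and 24 lower. The 6 low-background histone genes were called higher, also over the list alone, with a median of 1.18 (camera adjusted p = 2.5e-16, adjusted p = 0.0260 with an estimated correlation). HIST1H2AC went from 6.68 ± 1.35 CPM in WT to 28.6 ± 2.72 in KO (2.10 ± 0.12, edgeR adjusted p = 4.1e-09), the linker histone HIST1H1C from 30.7 ± 2.58 to 103 ± 8.43 (1.75 ± 0.07, adjusted p = 1.2e-10) and HIST1H2BK from 98.5 ± 2.14 to 229 ± 3.85 (1.22 ± 0.04, adjusted p = 3.9e-11). Of these 6, 3 meet the background limit against the lowest group mean, and all 3 were called higher (median 1.21). All 7 immediate early genes were called higher, over the list alone as well, with a median of 0.72 (camera adjusted p = 5.3e-08, adjusted p = 0.0803 with an estimated correlation). They include the stress-induced factor ATF3, at 40.7 ± 0.734 CPM in WT and 94.8 ± 7.8 in KO (1.22 ± 0.06, adjusted p = 1.5e-09), and the AP-1 genes FOSL2 (0.80 ± 0.09) and JUN (0.72 ± 0.05). Of the 7 immediate early genes, 5 meet the background limit against the lowest group mean. All 5 were called higher, with a smaller median of 0.39.

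Ribosomal protein genes were slightly higher in KO: 62 of 76 were called higher and 6 lower (64 and 6 over the list alone), with a median of 0.23, or 0.17 with the background subtracted and 0.10 with it subtracted at 2 times its estimate (camera adjusted p = 4.3e-12, adjusted p = 0.599 with an estimated correlation). RPL9 and RPL5, of the large subunit, each rose by 0.40 ± 0.04. RPS6, RPL35 and RPL7A, all on chromosome 9, were lower (-0.23, -0.21 and -0.20), with folds of 0.13, 0.15 and 0.16 in the scaling over all genes. Of 22 ATF4 and unfolded protein response genes 13 were called higher and 6 lower (the same over the list alone), with a median of 0.18 (camera adjusted p = 0.00678, adjusted p = 0.261 with an estimated correlation). The amino acid transporter genes SLC3A2 (0.76 ± 0.05) and SLC7A5 (0.58 ± 0.07) rose, and the serine synthesis gene PSAT1 fell (-0.38 ± 0.04).

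Structural genes were divided in KO against WT. Of 8 epithelial genes 5 were called higher and 1 lower (6 and 1 over the list alone), with a median of 0.25 (camera adjusted p = 0.0117, adjusted p = 0.136 with an estimated correlation). The simple-epithelium keratins KRT8 (0.67 ± 0.06) and KRT18 (0.63 ± 0.04) rose, and the tight junction gene CLDN7 fell (-1.12 ± 0.12). Of 15 mesenchymal and invasion genes 6 were called higher and 4 lower (8 and 4 over the list alone), with a median of 0.11, or 0.02 with the background subtracted at 2 times its estimate (camera adjusted p = 0.0117, adjusted p = 0.268 with an estimated correlation). VIM, the mesenchymal intermediate filament, rose from 881 to 1.79e3 CPM (1.02 ± 0.06, edgeR adjusted p = 5.5e-09), and SPARC, a matrix glycoprotein, rose by 0.55 ± 0.04. Of 11 collagen and matrix genes 7 were called lower and 2 higher (8 and 2 over the list alone), with a median of -0.35, or 0.02 in the scaling over all genes (camera adjusted p = 0.0112, adjusted p = 0.261 with an estimated correlation). With the background limit against the lowest group mean the collagen list kept 8 genes and was not past the test (camera adjusted p = 0.558). COL6A1 (-0.89 ± 0.07) and LAMB1 (-0.84 ± 0.04) fell, while the basement membrane collagen COL4A2 rose (0.49 ± 0.05).

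Single genes with larger folds came from several pathways. IRS4 (chromosome X, 108732497-108736377, minus strand), an adaptor of insulin signalling, fell from 1.14e3 ± 32.3 to 283 ± 64.3 CPM (-2.01 ± 0.16, edgeR adjusted p = 4e-05). ID3 (-1.34 ± 0.13) and ID2 (-1.19 ± 0.10), inhibitors of DNA binding downstream of BMP signals, the neural factor POU3F2 (-1.21 ± 0.11), the Hippo pathway factor TEAD2 (-1.17 ± 0.08) and the recombination gene RAD54L (-1.15 ± 0.06) also fell. The stress gene GADD45B (1.61 ± 0.11), the lipid carrier APOE (1.48 ± 0.08) and the metalloproteinase inhibitor TIMP3 (1.25 ± 0.08) rose. The basal keratin KRT17 rose by 3.49 ± 0.48 (adjusted p = 0.0011), with 196 ± 120 CPM across the KO libraries against 17.3 ± 2.45 in WT. Outside the low-background genes, FAM83E went from 4.89 ± 3.74 to 53.4 ± 3.31 CPM (3.43 ± 0.50, adjusted p = 0.0012).

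Among genes of the 3' end machinery, 8 of 21 cleavage and polyadenylation genes were called higher and 3 lower (the same over the list alone; median 0.10, camera adjusted p = 0.238). NUDT21, which selects upstream UGUA elements, rose by 0.19 ± 0.03 and the nuclear poly(A)-binding gene PABPN1 by 0.39 ± 0.07, while CPSF4 was lower (-0.32 ± 0.05), with a fold of 0.04 in the scaling over all genes. INTS1, an Integrator scaffold, fell by 0.51 ± 0.05, and of the 2 Integrator genes in this set 1 was called. Histone pre-mRNA processing (3 higher, 0 lower of 8, 1 and 0 over the list alone, camera adjusted p = 0.505), cell cycle (9 and 6 of 29, 0.546), p53 targets (7 and 2 of 16, 0.128), the anaphase-promoting complex (2 and 5 of 13, 0.546) and the proteasome (13 and 7 of 31, 0.128) were not past the camera test. Neither were heat shock (7 and 1 of 15, camera adjusted p = 0.128), interferon-stimulated (1 and 4 of 18, 0 and 0 over the list alone; 0.125), TGF-beta and YAP (3 and 2 of 8, 0.546), hypoxia (8 and 4 of 21, 0.508), respiratory chain (7 and 5 of 30, 0.546) and HECT ligase genes (1 and 2 of 8, 0.844).

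**Figure D2:**
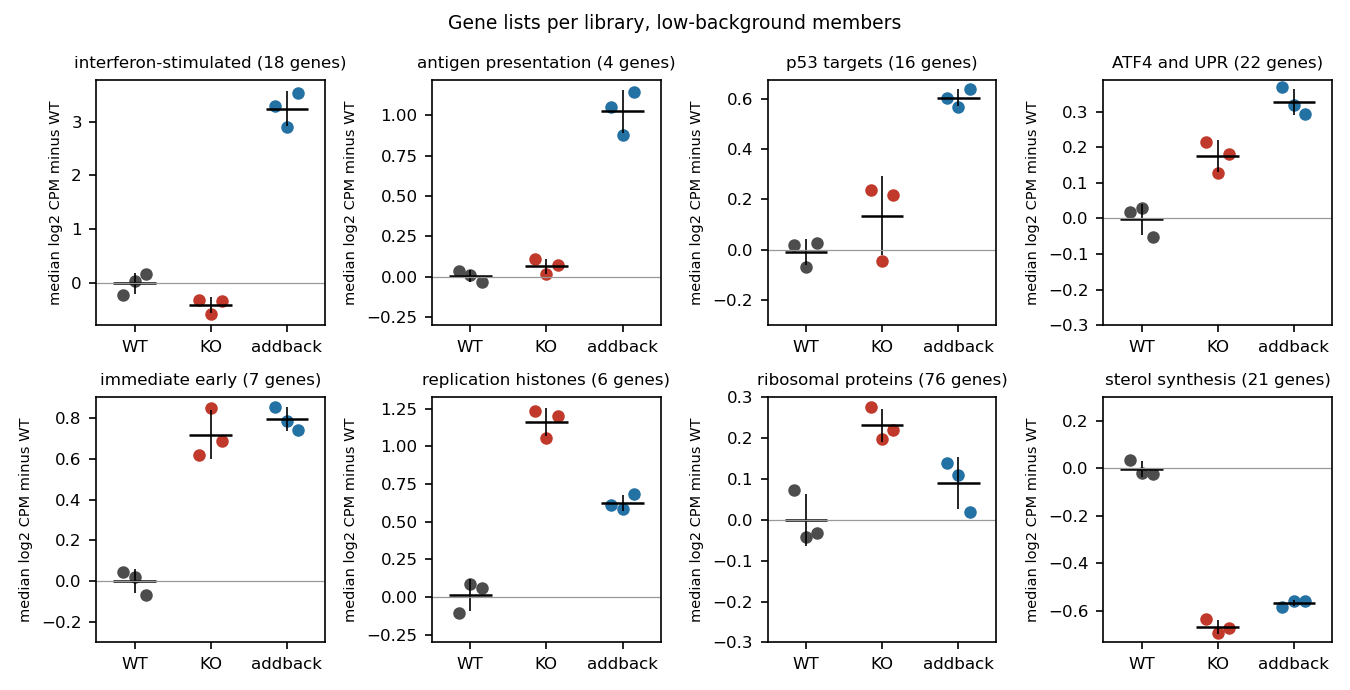
Median log2 scaled CPM of 8 gene lists in each library of KO, addback and WT, minus the WT mean; each point is a library and each list holds the low-background members given on its panel. Interferon-stimulated genes lay at 2.89 to 3.54 in addback libraries, and sterol genes at -0.69 to -0.64 in KO and -0.58 to -0.56 in addback.

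Interferon-stimulated genes were the largest difference between addback and KO cells. IFIT2 (chromosome 10, 89301949-89309276, plus strand), which binds viral RNA, rose from 1.75 ± 0.0979 CPM in KO to 626 ± 200 in addback (8.47 ± 0.43, edgeR adjusted p = 2.6e-05), and IFIT1 from 5.82 ± 0.596 to 1.08e3 ± 227 (7.54 ± 0.27, adjusted p = 4.2e-06). IRF9, a transcription factor of the response, rose from 22.4 to 146 ± 10 CPM (2.70 ± 0.08, edgeR adjusted p = 4e-12). All 18 interferon genes were called higher, over the list alone as well, with a median of 4.19 (camera adjusted p = 1.0e-112, adjusted p = 0.00928 with an estimated correlation). Of these 18, 1 meets the background limit against the lowest group mean. They include the ubiquitin-like ISG15 (4.68 ± 0.17), the antiviral RSAD2 (7.21 ± 0.59) and the RNA sensor DDX58 (4.63 ± 0.31). All 4 low-background antigen presentation genes were called higher (median 0.72), with HLA-F at 1.41 ± 0.07 and B2M, the light chain of class I HLA, at 0.69 ± 0.05. Outside the low-background genes, OAS1, IFI44L and IFI44 had log2 folds of 10.35, 10.73 and 9.92 in the scaling over all genes.

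Targets of p53 and ATF4 were higher in addback than in KO. Of 16 p53 targets 15 were called higher and 0 lower (16 and 0 over the list alone), with a median of 0.39, or 0.06 in the scaling over all genes (camera adjusted p = 6.9e-07, adjusted p = 0.430 with an estimated correlation). FDXR, a mitochondrial ferredoxin reductase, rose by 0.89 ± 0.08 and SESN2, a sensor of leucine, by 0.63 ± 0.08. Of 22 ATF4 genes 12 were called higher and 0 lower (15 and 1 over the list alone), with a median of 0.21, or -0.13 in the scaling over all genes (camera adjusted p = 1.3e-05, adjusted p = 0.157 with an estimated correlation). DDIT3, the CHOP factor of the unfolded protein response, rose by 0.71 ± 0.08 and the asparagine synthetase gene ASNS by 0.42 ± 0.05. Of 7 immediate early genes 4 were called higher and 0 lower (4 and 1 over the list alone), with a median of 0.22, or -0.12 in the scaling over all genes (camera adjusted p = 0.0445, adjusted p = 0.570 with an estimated correlation).

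Low-background histone, ribosomal and mesenchymal genes were lower in addback than in KO. All 65 tested histone genes together went the other way in the scaling over all genes, with a median of 1.02, 23 called higher and 7 lower (camera adjusted p = 0.612). The 6 low-background histone genes were all called lower, over the list alone as well, with a median of -0.51 (camera adjusted p = 6.2e-06, adjusted p = 0.157 with an estimated correlation), among them HIST1H2BK (-0.68 ± 0.04) and HIST1H2AC (-0.64 ± 0.11). Of 76 ribosomal protein genes 50 were called lower and 1 higher (54 and 1 over the list alone), with a median of -0.16, or -0.09 with the background subtracted and -0.02 with it subtracted at 2 times its estimate (camera adjusted p = 4.1e-09, adjusted p = 0.609 with an estimated correlation). RPL5 fell by 0.27 and RPSA fell by 0.25, and RPL36A rose by 0.58. Of 15 mesenchymal genes 9 were called lower and 1 higher, the same over the list alone, with a median of -0.16, or -0.08 with the background subtracted at 2 times its estimate (camera adjusted p = 0.0246, adjusted p = 0.390 with an estimated correlation), and VIM fell by 0.46 ± 0.06. Of 11 collagen and matrix genes 6 were called higher and 3 lower, the same over the list alone, with a median of 0.30, or -0.04 in the scaling over all genes (camera adjusted p = 0.0105, adjusted p = 0.315 with an estimated correlation). AGRN, a heparan sulfate proteoglycan, rose by 0.91 ± 0.05.

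Smaller shifts covered metabolism and division. Sterol genes had 7 called higher and 1 lower of 21 (9 and 1 over the list alone), with a median of 0.10, or -0.25 in the scaling over all genes (camera adjusted p = 0.0406, adjusted p = 0.609 with an estimated correlation). INSIG1 rose by 0.38 ± 0.05. Hypoxia and glycolysis genes had 8 higher and 2 lower of 21 (9 and 2 over the list alone), with a median of 0.08, or -0.26 in the scaling over all genes (camera adjusted p = 0.0406, adjusted p = 0.288 with an estimated correlation). The angiogenic factor VEGFA rose by 0.55 ± 0.05 and the glucose transporter gene SLC2A3 by 0.68 ± 0.07. Cell cycle genes had 5 higher and 12 lower of 29, the same over the list alone, with a median of -0.08, or -0.03 with the background subtracted at 2 times its estimate (camera adjusted p = 0.0406, adjusted p = 0.609 with an estimated correlation). PLK1, the mitotic kinase, fell by 0.28 and CCNB1 fell by 0.26. Proteasome genes had 1 higher and 9 lower of 31 (1 and 8 over the list alone), with a median of -0.06, or 0.03 with the background subtracted at 2 times its estimate (camera adjusted p = 0.0406, adjusted p = 0.609 with an estimated correlation). Respiratory chain genes had 2 higher and 10 lower of 30, the same over the list alone, with a median of -0.08, or -0.0039 with the background subtracted at 2 times its estimate (camera adjusted p = 0.0427, adjusted p = 0.609 with an estimated correlation). With the background limit against the lowest group mean, the collagen, cell cycle, proteasome and respiratory chain lists each had a camera adjusted p of 0.0885 and the hypoxia list one of 0.139, so these calls were lost. Without addback library 2 the number of called lists fell from 13 to 6, without addback 3 to 7.

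Single genes followed both directions. The tight junction gene CLDN7 (1.39 ± 0.11), ID3 (1.60 ± 0.13) and ID2 (1.01 ± 0.10) rose from KO to addback. PMEPA1, a TGF-beta target, fell from 79.9 to 46.4 CPM (-0.78 ± 0.08, edgeR adjusted p = 2.7e-06), and the chaperone CLU (-0.78 ± 0.09), the adhesion gene CEACAM19 (-0.66 ± 0.07) and the myosin gene MYH9 (-0.57 ± 0.12) fell. KRT17 was not past the test (-1.13 ± 0.41, adjusted p = 0.073), and passed it without KO 2 (-0.51, adjusted p = 0.000549) or KO 3 (-1.38, adjusted p = 0.0446). Cleavage and polyadenylation (3 higher and 7 lower of 21, the same over the list alone, camera adjusted p = 0.212), histone processing (0 and 1 of 8, 0.629), epithelial (2 and 2 of 8, 0.900), anaphase-promoting complex (1 and 4 of 13, 0.537), heat shock (4 and 6 of 15, 0.666), TGF-beta and YAP (2 and 2 of 8, 0.981), fatty acid (5 and 2 of 10, 0.502) and HECT ligase genes (0 and 0 of 8, 0.780) were not past the camera test.

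Addback cells differed from WT cells most in interferon-stimulated genes. IFIT2 stood 6.74 ± 0.37 above WT (edgeR adjusted p = 1.7e-05) and IFIT1 6.36 ± 0.25 (adjusted p = 2.3e-06). All 18 interferon genes were called higher (18 over the list alone), with a median of 3.27 (camera adjusted p = 1.2e-72, adjusted p = 0.0112 with an estimated correlation), and all 4 antigen presentation genes were called higher, with a median of 1.03. Only 1 of the 18 meets the background limit against the lowest group mean. The others enter through a mean that their addback level raises, which favours such calls. All 34 tested interferon genes had a median of 3.10 in the scaling over all genes. Sterol genes were lower: 20 of 21 were called lower and 0 higher, the same over the list alone, with a median of -0.57 (camera adjusted p = 6.2e-31, adjusted p = 0.0112 with an estimated correlation). INSIG1 (-1.08 ± 0.05), HMGCS1 (-0.86 ± 0.05) and ACAT2 (-0.84 ± 0.04) were below WT, as was IRS4 (-1.33 ± 0.16). Of 22 ATF4 genes 15 were called higher and 2 lower (16 and 2 over the list alone; median 0.31, camera adjusted p = 2.1e-12, adjusted p = 0.0112 with an estimated correlation), with DDIT3 at 1.33 ± 0.08 and SLC3A2 at 1.06 ± 0.05. All 7 immediate early genes (median 0.78, camera adjusted p = 2.1e-14, adjusted p = 0.0112 with an estimated correlation) were called higher, also over the list alone, with ATF3 at 1.83 ± 0.06. With the replicate number as a block the adjusted p with an estimated correlation was 0.0570 for immediate early genes, so that call was lost, and 0.0284 for interferon, sterol and ATF4 genes.

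Targets of p53 were above WT in addback: 14 of 16 were called higher and 0 lower, the same over the list alone, with a median of 0.61 (camera adjusted p = 6.0e-10, adjusted p = 0.249 with an estimated correlation). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose by 1.36 ± 0.10 (edgeR adjusted p = 1.9e-06), BBC3, which codes for the death factor PUMA, by 0.88 ± 0.09 and AEN by 0.76 ± 0.07. Of the 6 low-background histone genes 5 were called higher and 0 lower, the same over the list alone (median 0.64, camera adjusted p = 1.5e-06, adjusted p = 0.0665 with an estimated correlation), with HIST1H2AC at 1.46 ± 0.13. All 65 tested histone genes had a median of -0.04 in the scaling over all genes, with 4 called higher and 0 lower (camera adjusted p = 0.257). Of 8 epithelial genes 5 were called higher and 0 lower (6 and 0 over the list alone; median 0.31, camera adjusted p = 0.0041, adjusted p = 0.0665 with an estimated correlation), with the adhesion gene EPCAM at 0.50. Of 21 hypoxia genes 9 were called higher and 1 lower (10 and 1 over the list alone; median 0.10, camera adjusted p = 0.00789, adjusted p = 0.0714 with an estimated correlation), with VEGFA at 0.81 ± 0.06. Of 76 ribosomal protein genes 22 were called higher and 5 lower (19 and 4 over the list alone; median 0.09, camera adjusted p = 0.0487, adjusted p = 0.868 with an estimated correlation), with RPS19 at 0.34 and RPS6 at -0.39.

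Lists not past the camera test in addback against WT were cleavage and polyadenylation (2 higher and 2 lower of 21, 0 and 0 over the list alone, camera adjusted p = 0.848), histone processing (1 and 0 of 8, 0.755), mesenchymal (6 and 4 of 15, 0.575), collagen and matrix (2 and 5 of 11, 0.667), cell cycle (6 and 11 of 29, 0.325) and the anaphase-promoting complex (0 and 6 of 13, 0.296). The proteasome (7 higher and 7 lower of 31, camera adjusted p = 0.886), heat shock (5 and 2 of 15, 0.296), TGF-beta and YAP (2 and 0 of 8, 0.621), respiratory chain (2 and 7 of 30, 0.325) and HECT ligase genes (1 and 1 of 8, 0.694) were not either. Fatty acid genes (2 higher and 7 lower of 10; median -0.25) had a camera adjusted p of 0.0579, or 0.0341 with the replicate number as a block (adjusted p = 0.482 with an estimated correlation). With that block 2735 low-background genes were called (1313 higher, 1422 lower), 2360 of them also without it. Over all tested genes the block raised the count from 566 to 1535 (965 higher, 570 lower), with 561 called both ways. The 566 became 852 without addback 1 (232 higher, 620 lower), 270 without addback 2 (187 and 83) and 324 without addback 3 (198 and 126). Without WT 1, 2 and 3 in turn it became 767 (625 and 142), 563 (309 and 254) and 679 (250 and 429). The split by direction thus reversed without addback 1 or WT 3.

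Outside the low-background genes, TMEM47, FAM84A and ZNF160 were low in KO cells and still below WT in addback cells. TMEM47 (chromosome X, 34627064-34657288, minus strand), a junction protein, stood at 44.5 ± 3.11 CPM in WT, 0.532 ± 0.0941 in KO and 1.95 ± 0.62 in addback, and its log2 fold in addback against WT was -4.49 in the scaling over all genes. FAM84A (chromosome 2, 14632686-14640044, plus strand) stood at 71.9 ± 2.3, 6.80 ± 2.02 and 12.4 ± 0.181 CPM. The zinc finger gene ZNF160 (chromosome 19, 53066614-53103434, minus strand) stood at 40.5 ± 10.2, 0.572 ± 0.107 and 10.4 ± 5.44 CPM, with log2 folds of -5.77 in KO against WT and -1.96 in addback against WT (edgeR adjusted p = 0.00789). All 3 were called higher in addback than in KO in the scaling over all genes (FAM84A by 0.52 and ZNF160 by 3.81, for instance), calls that were lost with the background subtracted. With it subtracted at 2 times its estimate ZNF160 was past the test in the opposite direction (-6.59, edgeR adjusted p = 0.00477). For FAM84A the call was also lost without KO 1 (edgeR adjusted p = 0.0554), KO 2 (0.123), addback 1 (0.154), addback 2 (0.0782) or addback 3 (0.0676). The estimated coding background of ZNF160 in addback was 9.43 CPM of its 10.4.

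**Figure D3:**
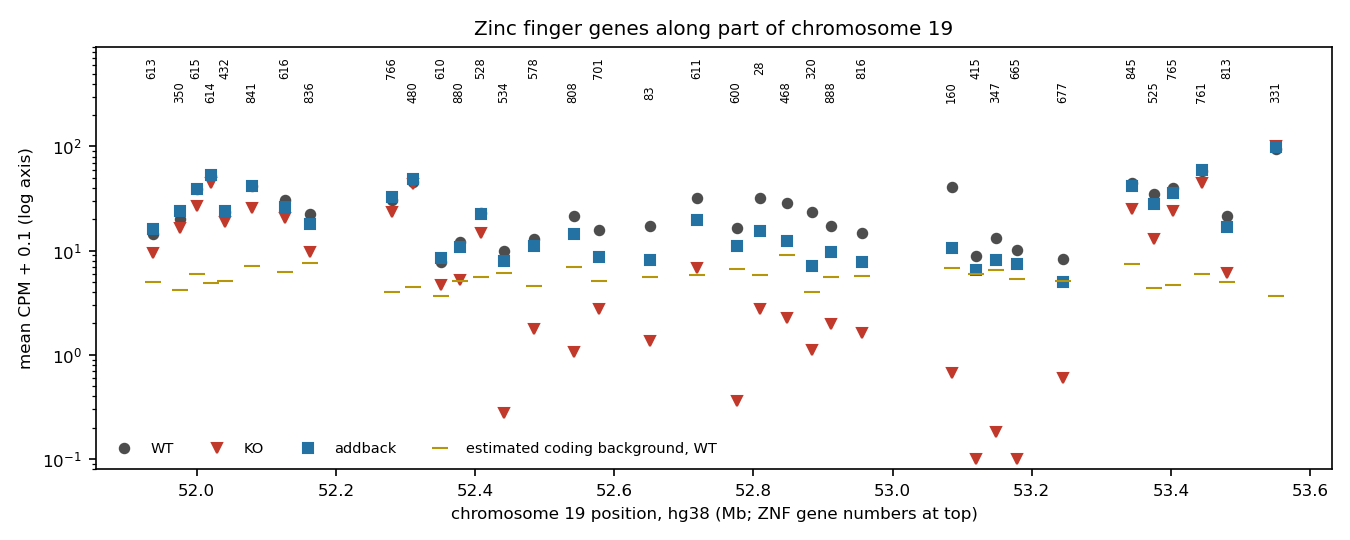
Mean scaled CPM + 0.1 (log axis) of zinc finger genes along chromosome 19 in WT, KO and addback, 3 libraries each. The yellow dash is the estimated coding background of WT in CPM of library totals, not in scaled CPM. It therefore lies too low on this axis (6.68 for ZNF160, against 9.36 in scaled CPM). The 11 genes from ZNF808 to ZNF160 sum to 258 CPM in WT, 21.7 in KO and 124 in addback. Directly beside them, ZNF578 (12.7 CPM in WT, 1.68 in KO) and ZNF415 (8.81 and 0) were also lower in KO. ZNF480, several genes away, stood at 45.7 in WT, 43.5 in KO and 48.6 in addback.

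Of the 3046 low-background genes called in KO against WT, 1306 (42.9%) were returned by addback, 614 from higher and 692 from lower in KO. Independent lists would give 253 and 312, and 159 genes were called in the same direction in both comparisons. The covariance of both folds was -0.0437, against -0.0019 in 20 simulated sets of unchanged groups sharing the KO libraries. Those sets hold no changed genes, so hardly any gene can be called in them. Their 0 returned genes were fixed in advance and give no baseline for the 1306. The 3 KO libraries cannot be divided into sets of at least 2, so part of the excess may come from these shared libraries. The simulated sets do not hold the correlation of same-number WT and addback libraries, which can add to both the covariance and the returned genes. All 3 KO libraries had an estimated background of 0%, against 2.85% to 14.9% in WT and addback libraries. A library batch that sets KO apart from both other groups would also give returned genes. Such a batch cannot be told apart from genotype in either comparison with KO. Still called in addback against WT with the same sign were 1593 genes (52.3%). The low-background histone genes were returned in 6 of 6 cases and 5 of them were still above WT. Of 19 called sterol genes 7 were returned and 19 were still below WT, and of 7 immediate early genes 0 were returned and 7 were still above WT. Of 68 called ribosomal protein genes 46 were returned and 26 were still called against WT with the same sign. Of 11 cleavage and polyadenylation genes these counts were 9 and 2. RAD54L stood at 104 CPM in WT, 47.1 in KO and 104 in addback. Over all tested genes 11291 of 13542 (83.4%) were returned, 3664 and 7627 by direction, where independent lists would give 1158 and 3129. There 50 were called in the same direction, and the covariance was -8.71 against -0.109 simulated. Background reads that the KO libraries lack would produce such returned calls by themselves. The share was 54.0% with the background subtracted and 50.04% with it subtracted at 2 times its estimate.

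Genes on chromosome 9 were lower in both KO and addback cells than in WT cells. Of 211 low-background genes there, 199 were called lower in KO and 1 higher (94.3% lower, against 25.5% on the other chromosomes), with a median of -0.45, a ratio of 0.732 (camera adjusted p = 2.4e-48, adjusted p = 0.0055 with an estimated correlation). In addback against WT 196 of 211 were lower (median -0.41, adjusted p = 0.0039 with an estimated correlation), and in addback against KO 46 were higher and 34 lower (median 0.01). Medians over 20 Mb windows along the chromosome ran from -0.57 to -0.39. Chromosome 7 genes were lower as well, 166 of 253 in KO (median -0.21, camera adjusted p = 2.2e-12, adjusted p = 0.0012 with an estimated correlation) and 166 in addback (median -0.22, adjusted p = 3.8e-04 with an estimated correlation). Chromosome 6, which carries UBE3D, had a median of -0.12 in KO against WT, with 148 of 301 genes lower (camera adjusted p = 0.000822). In addback against WT it had -0.11, with 131 lower (camera adjusted p = 0.00425). With an estimated correlation its camera adjusted p was 0.27 and 0.507. Chromosome 14 had medians of 0.10 in KO against WT (85 of 199 higher) and 0.12 in addback against WT (83 higher). Its camera adjusted p with an estimated correlation was 0.101 and 0.0446. Chromosome 2 had -0.07 and -0.09 (camera adjusted p = 0.0872 and 0.0137, or 0.742 and 0.604 with an estimated correlation). Folds given above for single genes and lists include the shift of their chromosome, as for RPS6 on chromosome 9 and INSIG1 on chromosome 7.

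**Figure D4:**
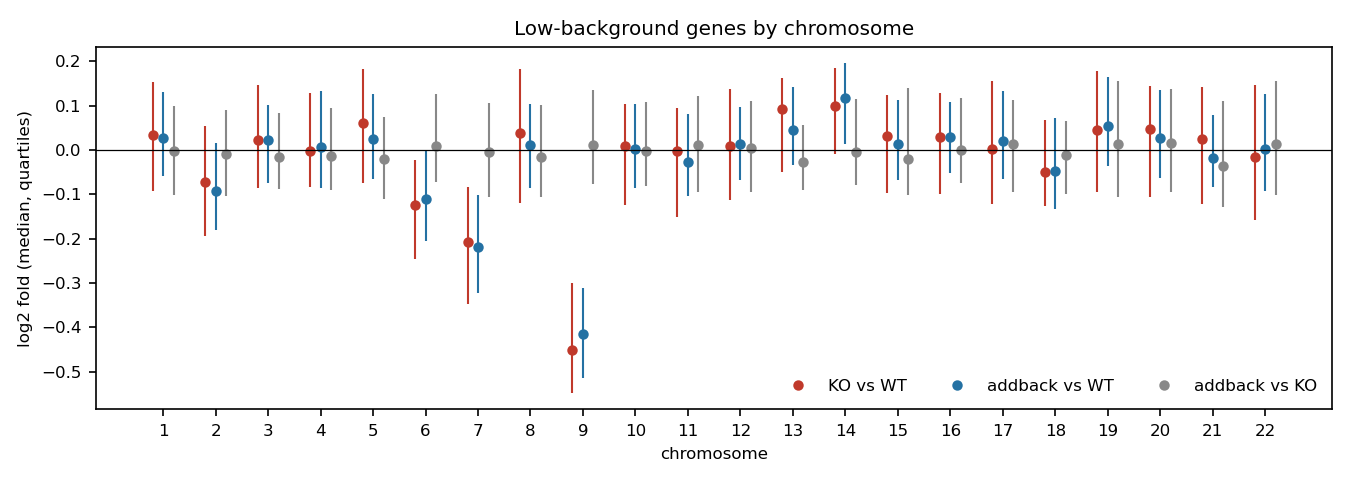
Median log2 fold (points) and quartiles (bars) of low-background genes on each chromosome in KO against WT, addback against WT and addback against KO. Chromosome 9 lay at -0.45 and -0.41 in the comparisons with WT and at 0.01 in addback against KO.

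Readthrough regions downstream of genes moved in both directions in the authors' deposited tables. How those folds were scaled between libraries is not given. Scaling on the regions themselves would remove a shift common to all of them, so an even split does not exclude one. Of 2541 regions in the authors' deposited table of KO against WT, 1265 were called, 631 higher (median 0.64) and 634 lower (median -0.52). The highest folds in the authors' deposited table followed the splicing gene SNRPA (2.55 ± 0.10), the ribosomal protein genes RPL3 (2.54 ± 0.13) and RPS19 (1.97 ± 0.06), and the histone genes HIST1H2AC (2.03 ± 0.09) and HIST1H4H (1.96 ± 0.10). The SNRPA region covers 40765393-40775178 on chromosome 19, plus strand. The lowest in the authors' deposited table followed IRS4 (-2.61 ± 0.14), HERC2P10 (-2.60), LINC01061 (-2.25), CKMT1A (-2.08) and CBY3 (-1.71). Scaled on low-background genes, the hosts of the highest regions had edgeR folds of 0.13, 0.22, 0.33, 2.10 and 1.12 in the order named. Those of the lowest had -2.01, -2.75, 0.07, -0.81 and -3.91. The regions after HIST1H2AC, HERC2P10 and CBY3 thus moved no farther than their host genes. In the authors' deposited table, 15 of 22 regions after ribosomal protein genes were called higher and 0 lower (median 0.56, against 0.61 for their host genes in the edgeR scaling over all genes and 0.25 scaled on low-background genes).

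The authors' deposited table of addback against KO holds 2396 regions, of which 817 were called, 445 higher (median 0.44) and 372 lower (median -0.45). Higher in the authors' deposited table were regions after the interferon-induced SP110 (3.26 ± 0.21), SLFN5 (2.17) and IRF9, and after CKMT1A (2.01) and CBY3 (1.79). Lower in the authors' deposited table were those after RPL3 (-1.35), SOX4 (-1.17), XRCC5 (-1.11), RPL14 (-1.09) and ITGB1 (-0.97). Scaled on low-background genes, the hosts of the higher regions had edgeR folds of 3.33, 2.21, 2.70, 1.46 and 3.26 in the order named. Those of the lower regions had -0.17, -0.00013, -0.10, -0.18 and -0.22. Of 9 regions after interferon-stimulated genes, 0 exceeded the fold of their host, though the authors' folds in this comparison were shrunken. Called in opposite directions in both of the authors' deposited tables were 625 regions (49.4% of 1265), 293 from higher in KO and 332 from lower. Independent lists would give 98.0 and 118. Called in the same direction in the authors' deposited tables were 28. In 100 simulated draws with shared KO libraries and no changed regions, 0 were returned. That 0 was fixed in advance, since hardly any region can be called there, and gives no baseline for the 625. The draws also do not hold the correlation of same-number WT and addback libraries. Part of the excess may come from the shared KO libraries, or from a library batch that sets KO apart from both other groups.

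Regions called higher in the authors' deposited table of KO against WT exceeded the edgeR fold of their host gene by a median of 0.36 (95% interval 0.30 to 0.39), in 499 of 625 regions. With host folds scaled on low-background genes the difference to the authors' deposited table was 0.73 (600 of 625), and for low-background hosts alone 0.61 (364 of 371). Regions chosen by their own fold tend to differ from their hosts in that direction, and uncalled regions of the authors' deposited table differed by -0.19, or 0.18 with host folds scaled on low-background genes and 0.065 for low-background hosts. Regions called lower in the authors' deposited table differed from their hosts by a median of -0.43, or -0.05 with host folds scaled on low-background genes and -0.28 for low-background hosts. Regions higher in addback in the authors' deposited table differed by 0.30, or -0.05 with host folds scaled on low-background genes and 0.33 for low-background hosts. Regions lower in addback in the authors' deposited table differed from their hosts by -0.16 (283 of 369 below), or -0.47 for low-background hosts (250 of 253 below). Next genes were sought within 10 kb of the end of the host gene. Regions higher in the authors' deposited table had a median length of 11800 bases, so a next gene may start inside the region. The 102 next genes for higher regions had a median edgeR fold of 0.17 in the scaling over all genes. The 191 for uncalled regions had 0.18 (difference -0.00, 95% interval -0.15 to 0.16). Scaled on low-background genes these medians were -0.19 and -0.20. Random lists matched on expression had medians of 0.017 and 0.00034, and the genes after higher regions lay at percentile 99.54 of them, with a higher percentile after uncalled regions. The 83 next genes for lower regions of the authors' deposited table had a median of 0.13 (percentile 82.57), or -0.25 scaled on low-background genes. Low-background neighbours had medians of 0.04 after higher and 0.0093 after uncalled regions of the authors' deposited table (percentiles 80.9 and 71.58).

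**Figure D5:**
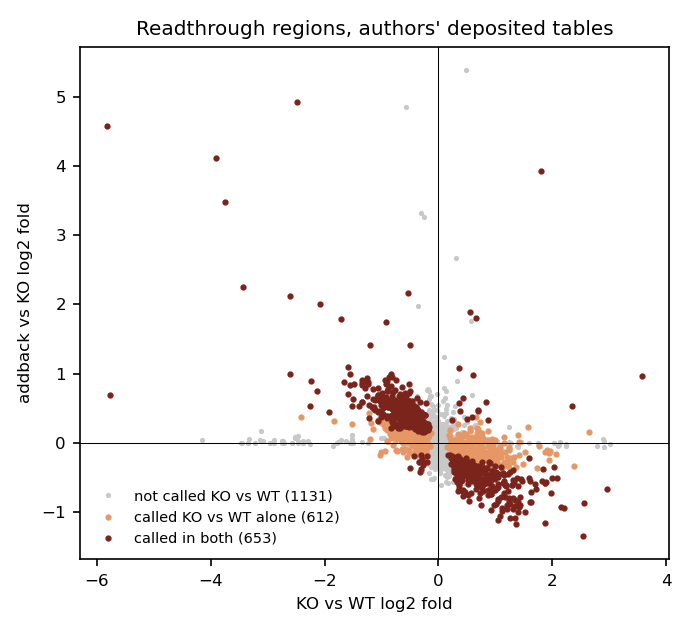
Authors' deposited log2 fold of each readthrough region in KO against WT (horizontal) and addback against KO (vertical); each point is a region, with 1131 not called in KO against WT, 612 called there alone and 653 called in both of the authors' deposited tables. Of the regions called in both, 625 moved in opposite directions and 28 in the same direction.

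Lists with fewer than 5 low-background members were counted in the scaling over all genes, where background reads raise the WT and addback levels. That scaling also puts the median low-background gene at 0.36 in KO against WT and -0.34 in addback against KO. Over all 21994 tested genes, 5315 were called higher and 8227 lower in KO against WT, and 8364 and 4791 in addback against KO. NF-kB genes had 2 called higher and 11 lower of 20 in KO against WT, 16 and 0 in addback against KO, and 3 and 0 (4 and 0 over the list alone) in addback against WT. Antigen presentation genes had 3 higher and 2 lower of 15, then 11 and 0, then 9 and 0 (13 and 0 over the list alone) in the same comparisons. Wnt targets had 4 and 3 of 17, 2 and 4, then 0 and 0. Stemness genes 6 and 5 of 17, 7 and 3, then 3 and 0, and neural genes 6 and 9 of 20, 9 and 2, then 3 and 0. Integrator genes had 5 higher and 0 lower of 15 in KO against WT, 0 and 7 in addback against KO, then 0 and 0. Their medians of 0.13 and -0.25 in the comparisons with KO were smaller in size than the 0.36 and -0.34 of low-background genes. The 2 low-background Integrator genes had a median of -0.25 in KO against WT. Kidney and adrenal genes had 2 and 14 of 21, 14 and 1, then 0 and 0. Breast epithelial genes 4 and 11 of 18, 11 and 3, then 1 and 0. Blood genes 0 and 10 of 15, 10 and 0, then 1 and 0, and endothelial genes 0 and 8 of 10, 8 and 0, then 0 and 0. Mitochondrially encoded genes had 0 members in the table. Over all genes 21, 19 and 13 of 31 lists passed the camera test in these comparisons, against 0, 1 and 3 with an estimated correlation (0 for addback against WT with the replicate block), and among low-background genes 9, 13 and 9 of 21, against 2, 1 and 4. Mean, median and camera direction did not share a sign for some lists. Over all genes the 65 replication-dependent histone genes had a median of -1.04 and a mean of -1.58 in KO against WT with an upward test (adjusted p = 0.977), and epithelial genes a median of 0.12 and a mean of 1.02 in addback against KO with a downward test. Over all genes the signs also differed for mesenchymal, epithelial, Wnt, fatty acid, hypoxia, stemness, neural and HECT ligase genes in KO against WT. They differed for mesenchymal, p53, ATF4, immediate early, TGF-beta, Wnt, fatty acid, hypoxia and HECT ligase genes in addback against KO, and for histone, collagen, proteasome, fatty acid and kidney genes in addback against WT. Among low-background genes they differed for epithelial, heat shock and TGF-beta genes in addback against KO and for mesenchymal and proteasome genes in addback against WT, none of them past the test.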

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

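Runs on low-background genes, with background subtracted, with a 5% background limit, with the limit held against the lowest group mean, without WT and addback libraries 2 and 3, without chromosome 9, and with the block on low-background genes were chosen after the data were seen. The run without libraries 2 and 3 keeps 1 WT and 1 addback library, whose spread is assumed to be that of the KO libraries. Apart from the added runs, where the set of genes, the number of libraries or the limit itself changes a count, the cause of a shift was not tested. Over all tested genes, the 13542 genes called in KO against WT became 7096 with the background subtracted, 5098 with it subtracted at 2 times its estimate, 3046 among low-background genes, 3393 there with the replicate block and 7556 at an absolute log2 fold of at least 1 (11124 to 15646 with a library left out). The 13155 of addback against KO became 5002, 3437, 2131, 2592 and 7509 in the same order, and 8617 at an adjusted p of 0.01 (10056 to 15631 with a library left out). The 566 of addback against WT became 978 with DESeq2 factors, 1553 with upper quartile factors, 1847 with the DESeq2 test, 196 with 6 libraries, 1535 with the block, 2747 without libraries 2 and 3. It became 1715 and 1969 with the background subtracted, 2062 scaled on low-background genes, 2362 among these, 2735 there with the block, 231 at 0.01 and 162 at a log2 fold of at least 1; leaving out a library gave 270 to 852. The 11291 returned genes became 3829 and 2551 with the background subtracted, 1306 among low-background genes, 1622 there with the block, 7451 at 0.01 and 7097 at a log2 fold of at least 1 (8618 to 13342 with a library left out).

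Of gene lists over all genes, the 21 called in KO against WT became 0 with an estimated correlation, 12 with the background subtracted at 2 times its estimate, 9 among low-background genes and 9 there with the block (18 to 21 with a library left out). The 19 of addback against KO became 1, 10, 13 and 12 (19 to 21 with a library left out). The 13 of addback against WT became 3 with an estimated correlation and 12 to 22 with a library left out, 22 without addback 1 and 20 without WT 3.

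Among low-background genes, the 3046 became 1790 at a 5% background limit and 39 at a log2 fold of at least 1 (2659 to 3035 with a library left out). The 2131 became 920 without libraries 2 and 3, 1236 at 5%, 1279 at an adjusted p of 0.01 and 48 at a log2 fold of at least 1 (1603 to 1881 with a library left out). The 2362 became 1127, 1558 at 5% and 61 at a log2 fold of at least 1 (1899 to 2384). The 1306 returned became 534 without libraries 2 and 3, 769 with the background subtracted at 2 times its estimate, 741 at 5%, 740 at 0.01 and 8 at a log2 fold of at least 1 (937 to 1406). The 9 lists of KO against WT became 2 with an estimated correlation and 5 at 5% (9 to 11 with a library left out). The 13 of addback against KO became 1, 6 at 5%, 6 with the limit against the lowest group mean, 4 without libraries 2 and 3, 8 with the background subtracted at 2 times its estimate and 6 to 11 with a library left out. The 9 of addback against WT became 4 with an estimated correlation (8 to 9).

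Same-number libraries of addback and WT were correlated (0.90, 0.61 and 0.74 over all genes), and the block changed 2 list calls in that comparison: ribosomal protein genes over all genes (camera adjusted p = 0.0105 with it, 0.126 without; 0.919 with an estimated correlation) and fatty acid genes among low-background genes (0.0341 and 0.0579). No other call at the preset correlation changed with it. With an estimated correlation, the 3 lists called over all genes became 0 with the block (lowest adjusted p = 0.0576, interferon genes), and the 4 among low-background genes became 3, as immediate early genes went from 0.0112 to 0.0570.

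The difference of UBE3D between KO and WT was -3.65 CPM with TMM factors, -7.19 on raw totals, -11.3 scaled on low-background genes and -4.65 to -2.72 with a library left out. For the authors' deposited regions, the 1265 called in KO against WT became 205 at a log2 fold of at least 1 and 809 at or above the median level. The 817 of addback against KO became 34 at a log2 fold of at least 1, and the 625 returned became 431 at an adjusted p of 0.01, 754 at an unadjusted p of 0.05, 606 without chromosome 9 and 536 without coding bases. All regions of the authors' deposited table lay -0.10 from their hosts, -0.036 with the authors' host folds and -0.19 at or above the median level. This reversed to 0.27 with hosts scaled on low-background genes, 0.18 for low-background hosts and 0.20 for these without coding bases. Regions higher in KO lay 0.36 above hosts in the authors' deposited table, or 0.47, 0.19, 0.73, 0.61 and 0.63 in the same order, and regions lower in addback -0.16, or -0.23, -0.12, -0.50, -0.47 and -0.47. Of 3312 values of 167 named genes in other settings, 66 were weaker, 6 stronger and 8 reversed. In addback against KO, TMEM47 reversed to -1.14 with the background subtracted and to -2.88 with it subtracted at 2 times its estimate, where FAM84A (-0.036) and ZNF160 (-6.59) reversed as well, ZNF160 past the test (edgeR adjusted p = 0.00477). RPS6 (0.13), RPL35 (0.15), RPL7A (0.16) and CPSF4 (0.045) reversed in KO against WT in the scaling over all genes.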

Other observations

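The tests written after the result was seen are the comparison of shares between libraries for coding-exon reads, the addback and subtraction tests of chromosome 9, the tests of all blood markers and of the library batch for the interferon genes, the zinc finger region, and the splits of libraries over low-background genes.

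A run of zinc finger genes on chromosome 19, chosen after the values were seen and outside the rule for naming genes, was low in KO cells and, above the background, also in addback cells. All 11 genes from ZNF808 (start 52527656) to ZNF160 (end 53103434) were called lower in KO than in WT over all tested genes, with a median log2 fold of -3.31, and their summed level was 21.7 CPM in KO against 258 in WT. Above the estimated coding background the sum was 165 CPM in WT and 30.6 in addback, 18.5% of WT, beside the 21.7 of KO, where the background is 0. All 11 were called higher in addback than in KO (log2 folds of 1.16 to 4.97), much of it within the estimated coding background, and 1, ZNF160, was called lower than WT in addback. The ends of the run follow the chosen window. ZNF534 and ZNF578 before it and ZNF415 and ZNF347 after it were also called lower in KO. They stood at 8.81 to 13.2 CPM in WT and 0 to 1.68 in KO, and much of these WT levels may be coding background. ZNF761, farther along, stood at 57.4 CPM in WT, 44.4 in KO and 58.7 in addback. Reads of related zinc finger genes can be placed at the wrong copy. A change at this block in the KO line, such as silencing or lost copies, may explain it, as may an effect of UBE3D loss that the addback does not undo, and no value here separates them. DNA copy number and methylation of the block in the KO, addback and WT cells would.

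Reads over tissue-restricted genes in WT and addback libraries could come from uniform DNA background, from UBE3D loss lowering them in KO, or from captured coding exons. A uniform background would scale with exon length, with a slope near 1 of log2 counts. The slope was 0.337 (SE 0.0452, 544 genes), which argues against it. The slope on coding length was 0.674 (SE 0.0506, 539 genes), higher but also below 1. The background estimate of each gene takes a slope of 1 on coding length, so it is approximate for single genes. An effect of UBE3D would be alike in all libraries of a genotype, but the share of counts over these genes varied 4.26-fold among addback libraries and 4.80-fold among WT libraries, which argues against it. Captured coding exons would leave long non-coding genes empty, and protein-coding genes silent in KO held 47.2 WT counts per kb against 0.405 for long non-coding genes, a ratio of 117 (2916 and 1332 genes), in line with an exome-type library mixed into these libraries. Counting the reads that cross exon edges into introns would test it further.

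Lower RNA of chromosome 9 genes could reflect fewer copies of the chromosome in the KO line, loss of UBE3D, or coding-exon reads in WT. Fewer copies would lower readthrough regions as well. Over the regions present in both of the authors' deposited tables, the KO against WT fold on chromosome 9 differed from that elsewhere by -0.54 (79 and 2317 regions). The difference was -0.52 over all regions of the KO against WT table, 85 of them on chromosome 9. Fewer copies would give this, but so may any cause that lowers the RNA of these genes. An effect undone by the addback would show a rise in addback against KO, but the median was 0.011 (95% interval -0.02 to 0.04, 211 genes), which argues against it. An effect of UBE3D loss that the addback does not undo would show no rise either, and stays open. With the background subtracted at 2 times its estimate the difference of chromosome 9 from the other genes was -0.45 (95% interval -0.48 to -0.41). This cannot decide on coding-exon reads, since these genes were chosen for a low background. Its median share was 5.55% of mean CPM on chromosome 9 and 4.62% elsewhere. Addback libraries hold coding-exon reads as well, so such reads would raise addback above KO. The median of 0.011 given above argues against them. Copy number from DNA of KO and WT cells would decide it, and chromosome 7 likely needs the same check.

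The rise of interferon genes in addback cells could come from coding-exon reads, blood cells, a library batch or the addback itself. The median rise was 138 CPM over 34 genes against a background of 5.20, a ratio of 26.5, which argues against coding-exon reads. A batch shared with WT would leave addback and WT alike. The 34 genes lay a median log2 fold of 3.10 above WT in the scaling over all genes, which argues against such a batch. The 18 low-background ones lay 3.27 above WT, but only 1 of them meets the background limit against the lowest group mean. For blood cells the criterion written before, that the most abundant blood marker rises to at least 10% of the median interferon level, was met: the rise over KO was 20.6% of that level for CD68 (14.4 CPM in KO, 46.1 in addback) and 13.2% for ITGAM. CD68 is also expressed outside blood and ITGAM already stood at 18.7 CPM in WT, so single markers were a poor criterion. A blood admixture would raise most markers, but over 15 markers the median addback against WT fold was 0.044 (95% interval -0.04 to 0.25). Above the coding background their median rise over KO was -0.18% of that of the interferon genes (95% interval -0.33% to 2.23%), with the rise of 8 of 15 markers, PTPRC among them, no larger than their background, and only CD68 at 10% or more. This argues against blood cells as the source of the whole rise, though CD68 rose over WT as well (14.4 CPM there) and a small share of blood RNA would not show. A response to the delivery of UBE3D, such as a viral vector, or to its excess may remain, and no library here can separate them. An empty vector and a catalytically dead UBE3D in KO cells would.

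Grouping by chance was tested by all 10 splits of 6 libraries into 3 and 3, which are too few for a share under 0.05. Every other split also mixes both genotypes on each side, which raises its spread. Few gene calls there were likely beforehand and give no baseline for the real groups. For genes the real groups gave 12206, 14109 and 196 calls in KO against WT, addback against KO and addback against WT, and 2940, 2434 and 2123 among low-background genes, with 0 at most in any other split (1 of 10 splits as large in each case). For lists over all genes the real groups gave 19, 18 and 16, and the highest other splits 17, 18 and 21, so 1, 4 and 4 of 10 splits had as many or more. Among low-background genes the real groups gave 10, 10 and 9 lists and the highest other splits 9, 9 and 10 (1, 1 and 3 of 10 with as many or more).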
